A study of Mus musculus with 6 samples.

How the data were processed

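RNA was measured by sequencing in whole hearts of mouse embryos at embryonic day 11.5, in 3 control libraries and 3 conditional knockout libraries. Per the labels' protocols, RNA was extracted with Trizol from 18 hearts of each genotype and libraries were made with an Illumina TruSeq kit. The series text states that the RNA of a genotype was combined and then portioned into the 3 replicates, but the Xist and Afp values in the report differ between libraries of a genotype by more than portions of 1 pool would. How many hearts stand behind a library is therefore unclear, and p-values measure only the spread between these libraries.

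The deposited table holds FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) for 38918 genes, each row pairing an Ensembl identifier with a symbol. The submitters' processing notes name TopHat2 version 2.0.9, Cufflinks version 2.2.1, Cuffdiff and HTSeq, with no role or order, and the build mm10. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of near-identical paralogs, such as the globin genes, and of overlapping genes are uncertain. FPKM divides by transcript length and by a library total, so a few very abundant transcripts change the values of all other genes in a library.

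The table gives no read counts, and the absolute depth of the libraries is unknown. Where whole reads are counted, a gene's low values are multiples of what 1 read is worth, so ratios of low values between libraries pile up at 1 ratio. This was sought among genes under 0.3 FPKM in every library, in windows of 0.02 on the log2 scale, after a check on simulated reads. In the 6 pairs among replicates 2 and 3 of both groups, 9.9% to 17.2% of the genes lay at the modal ratio. In the 8 pairs that set a replicate 1 library against one of these, the share was 1.2% to 1.41%, and between both replicate 1 libraries it was 3.56%. Control replicate 2 was 1.474 times as deep as conditional knockout replicate 2 on this scale, control replicate 3 was 0.993 times as deep, and conditional knockout replicate 2 was 1.091 times as deep as conditional knockout replicate 3. No relative depth could be read for either replicate 1 library. Both were therefore treated as a separate technical batch in added alternatives, an assumption, as the share between them was also low.

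Values were analysed as log2(FPKM + 1), over the 12988 genes with a mean of at least 1 FPKM across the 6 libraries. Fold changes are conditional knockout minus control on that scale, which understates the change of low genes. The test was limma (version 3.58.1, in R 4.3.3) with an intensity trend and no block, with Benjamini-Hochberg adjustment and a threshold of 0.05, and counts were repeated for changes of at least 1.5-fold. The residual degrees of freedom were 4 and the prior degrees of freedom 3.33. Errors are SD over 3 libraries for FPKM and the moderated SE for log2 fold changes.

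A total of 32 gene lists, chosen for the endothelium, the myocardium, signalling pathways, and cell types or RNA that a heart sample can also hold, were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, were alternatives. Counts within a list are given over all genes tested and adjusted over the list alone.

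Before the data were examined, a rule fixed the genes to be named. It took Tek, Tie1, Angpt1, Angpt2 and Nfatc1, and up to 12 genes per direction with the largest change among those past the threshold with separated libraries and at least 2 FPKM in 1 group. It left out predicted and clone-named genes, and in this second part also erythroid and sex-linked genes. It further took up to 4 members per list past the threshold or, where none passed, the member with the highest mean, and the sex-linked genes in every library. Other genes named below were chosen after their values were seen. Gene positions come from GENCODE release M21 on GRCm38, the assembly behind mm10, in which 37607 of the 38918 identifiers were found.

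An exact 0 in this table can be a failed estimate. Of the 13 protein-coding mitochondrial genes, 7 were listed at 0 in all 6 libraries and 4 more in all 3 controls. A gene at 0 in every library of 1 group and above 5 FPKM in every library of the other is reported as listed at 0, with the value of each library and no fold.

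Both groups carry replicate numbers 1 to 3 in the labels. Deviations from the group means correlated between same-numbered libraries at 0.27, 0.11 and 0.44 for replicates 1, 2 and 3, over the 12805 tested genes above 0 in every library. Over all tested genes the values were 0.19, 0.031 and 0.23. Between control and conditional knockout libraries with different numbers, the first set of values lay between -0.39 and 0.095, so the pairing of replicate 2 is uncertain. The numbers were treated as a possible pairing of the libraries, on the first set of values. The main test has no block, and the blocked result is given where it changed a call.

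The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, rescaling to the total without blood and mitochondrial transcripts, no intensity trend, the replicate block and leaving out each library. Added after seeing the data were leaving out the genes listed at 0 in 1 group, a Y-linked covariate, a batch term for replicate 1, leaving out Tek, fry without the genes listed at 0, and replicates 2 and 3 alone. On simulated data for this comparison with 12988 genes, 200 of them changed, limma recovered 92.8% of genes changed by 2-fold and 99.4% of those changed by 4-fold, none with the wrong sign, with a mean of 8.6 false calls, averaged over 5 simulations. A list shifted by -0.5 was called in 5 of 5 simulations with the preset correlation and in 3 of 5 with the estimated one. The simulated noise was independent between genes and between libraries, without batches or pairs, and the 200 changed genes were drawn from the more abundant ones. These shares therefore do not give the recovery in the real libraries. Plots were drawn with matplotlib 3.10.9.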

Results

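Gene expression was profiled in whole hearts of mouse embryos at day 11.5 of gestation, when the ventricular wall is forming trabeculae and the inner lining of the heart, the endocardium, begins to contribute to coronary vessels. The control embryos carried 1 floxed and 1 wild-type allele of Tek, the gene for the angiopoietin receptor Tie2. The conditional knockout embryos carried 2 floxed alleles and a Cre recombinase driven from Nfatc1, a gene of the endocardium. Each group had 3 libraries, and the FPKM values summed to between 481330 and 582260 per library over 38918 listed genes. Between 12647 and 13041 genes reached 1 FPKM in a library, and read depth was unknown. The comparison asks which transcripts of the heart differ when Tie2 is removed from the endocardial lineage, with the title of the series naming sprouting and trabeculation as the processes of interest.

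Tek itself was measured first. The gene lies on chromosome 4 from 94739289 to 94874976 (GRCm38) and is protein coding. Its level was 21.6 ± 4.57 FPKM in control hearts (SD, n = 3) and 3.21 ± 0.142 FPKM in conditional knockout hearts (SD, n = 3), a 6.71-fold lower mean. The control libraries stood at 22.4, 25.7 and 16.6 FPKM and the conditional knockout libraries at 3.38, 3.13 and 3.13 FPKM, so that all 3 fell below every control. The log2 fold change was -2.40 ± 0.15 (SE, limma, adjusted p = 0.00131). Which exons the floxed allele removes is not given in the sources used here, and the FPKM covers the whole gene.

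Beyond Tek, 15 genes fell and a single gene with measurable levels in both groups, Esm1, rose in the test without a block. Under the replicate block, 10 of the 16 lower genes kept their calls and Esm1 did not. The 15 genes fell by 0.79 to 1.48 on the log2 scale, and in each of them the control and conditional knockout libraries did not overlap. Those with the largest changes were Prr15 at -1.48 ± 0.12 (SE, adjusted p = 0.00672), Gja4, which encodes connexin 37 of arterial endothelium, at -1.48 ± 0.16 (SE, adjusted p = 0.0232), and Gpr182, a receptor of endothelial cells, at -1.44 ± 0.12 (SE, adjusted p = 0.00672). The Iroquois transcription factor genes Irx6 and Irx5, which lie on chromosome 8 from 92674288 to 92680956 and from 92357625 to 92376286, changed by -1.33 ± 0.15 and -0.97 ± 0.11 (SE). Acap1, Lgals9 and the transmembrane collagen gene Col13a1 changed by -1.23, -1.06 and -1.01, and Bace2 changed by -0.79, the smallest of the 15. Esm1, which encodes the endothelial proteoglycan endocan, lies on chromosome 13 from 113209659 to 113218098. It went from 0.390 ± 0.04998 FPKM in controls to 2.34 ± 0.0552 FPKM in conditional knockouts (SD, n = 3 each), with a log2 fold change of 1.27 ± 0.14 (SE, adjusted p = 0.0219). Its call ended without any 1 library, at an adjusted p of 0.056, 0.135 and 0.0879 without control replicates 1, 2 and 3 and of 0.0943, 0.108 and 0.155 without conditional knockout replicates 1, 2 and 3, and also within replicates 2 and 3 (0.122) and with the Y-linked covariate (0.326), while its log2 fold change stayed between 1.24 and 1.29 without any 1 library.

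Over the 12988 genes tested, limma called 16 genes lower and 7 higher, and the counts were again 16 and 7 at a minimum of 1.5-fold. Of the 7 higher genes, 6 were listed at 0 in all 3 controls and are described further on, which leaves Esm1. At an unadjusted p under 0.05 in limma there were 567 lower and 300 higher genes, 867 in all. Other groupings of the libraries gave more. Control replicates 1 and 2 with conditional knockout replicate 1, set against the rest, gave 1276 such genes. With conditional knockout replicate 2 in its place the count was 902. This count therefore does not set the genotype apart from other differences between the libraries. The libraries of both groups were separated for 13.4% of the genes, where chance gives 10%. With the replicate number as a block, limma called 11 genes lower and 6 higher. The genes that lost the call under the block were Esm1 (adjusted p = 0.0921), Bace2 (0.102), Acap1, Irx5 and Irx6 (0.0604 each), Tmem100 (0.0542) and Col13a1 (0.0517). Within replicates 2 and 3 alone, treated as a technical batch inferred from the low values, 8 genes were lower, 6 of them among the 16. Tek then had an adjusted p of 0.0546, while replicate 1 holds 1 library per group and gives no value. Without any 1 library, 4 to 9 genes were lower: 9, 4 and 6 without control replicates 1, 2 and 3, and 6, 6 and 4 without conditional knockout replicates 1, 2 and 3. Gpr126, Bace2, Col13a1, Irx6 and Lgals9 lost their calls in all 6 fits without a library, at adjusted p values of 0.0607 to 0.311. Acap1, Ednrb, Irx5, Mmrn2 and Tmem100 kept theirs in 1 of the 6 fits without a library, Gja4 and Plvap in 2, Gpr182 in 3, Prr15 in 5, and Tek and Npr3 in 6. With no filter on low values 7 genes were lower, and with Y-linked expression as a covariate Tek alone was.

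**Figure D1:**
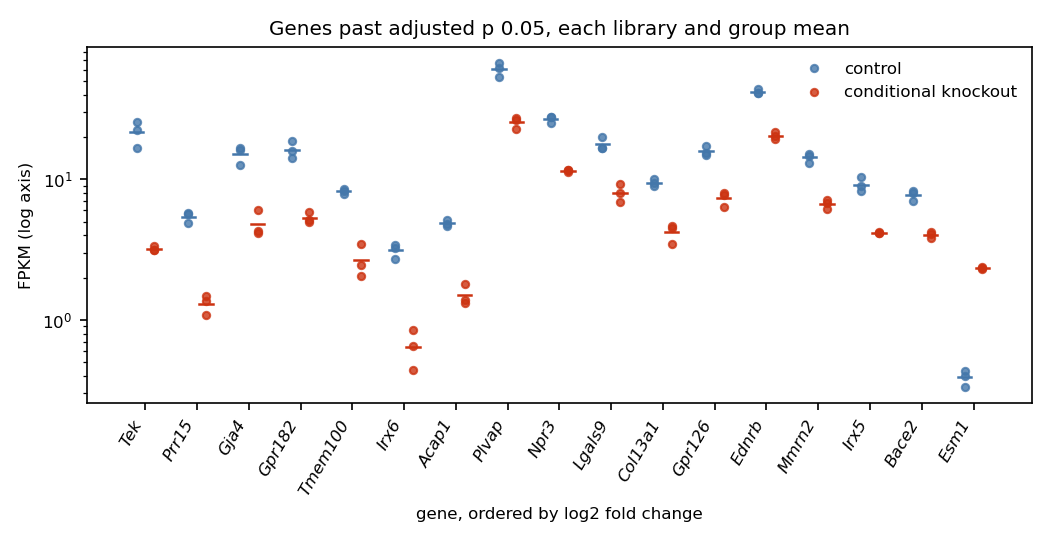
FPKM on a log axis for the 17 genes past the threshold that have values above 0 in both groups, ordered by log2 fold change; points are the 3 libraries of a group and bars are group means. Tek stands at 21.6 FPKM in controls against 3.21 FPKM in conditional knockouts, and Esm1, at the right, is the gene that is higher.

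Genes of the endocardium made up 5 of the 16 lower genes. Of 11 measured members of the endocardial list, 5 fell, 6 did not pass and none rose, with a median log2 fold change of -0.57. Tmem100, a membrane protein gene of endothelium responsive to BMP signals, went from 8.19 ± 0.326 to 2.66 ± 0.745 FPKM (SD, n = 3 each). Plvap, which forms the diaphragms of endothelial fenestrae, went from 60.7 ± 6.67 to 25.4 ± 2.51 FPKM, and Npr3, the clearance receptor for natriuretic peptides, from 26.7 ± 1.56 to 11.5 ± 0.243 FPKM. The adhesion receptor gene Gpr126 changed by -1.01 ± 0.11 (SE, adjusted p = 0.0245) and the endothelin receptor gene Ednrb went from 41.9 ± 1.58 to 20.4 ± 1.31 FPKM (adjusted p = 0.0113). Adjusted over the list alone, 8 members were lower, with Cgnl1, the flow-responsive Klf2 and Nfatc1 added. Nfatc1 was at 15.1 ± 0.923 FPKM in controls and 10.8 ± 0.959 FPKM in conditional knockouts (log2 fold change -0.44 ± 0.10, adjusted p = 0.333 over all genes). The Cre recombinase was driven from Nfatc1, and an effect of that allele on Nfatc1 itself was not tested apart from the loss of Tek. Emcn, an endomucin gene of veins and endocardium, stood at 45.6 ± 2.21 and 48.6 ± 7.95 FPKM, a difference within the spread. Camera placed the list below other genes (adjusted p = 2.6e-13 with the preset correlation), a call missed with an estimated correlation (adjusted p = 0.056).

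Of 24 genes shared by endothelial cells in general, Mmrn2, an extracellular matrix gene of endothelium, fell by 0.99 ± 0.10 on the log2 scale (SE, adjusted p = 0.0171), and 23 did not pass over all genes. The median log2 fold change was -0.28, with 20 members below 0 and 4 above. Adjusted over the list alone, 10 members were lower and 2 higher. Cdh5, the cadherin of endothelial junctions, was at 50.3 ± 5.95 and 30.4 ± 3.35 FPKM (log2 fold change -0.71 ± 0.13, adjusted p = 0.189), and Sox7 had a log2 fold change of -0.63 ± 0.09 (adjusted p = 0.0762). Robo4, at 0.74 ± 0.18, and Sox17, at 0.50 ± 0.15, were the members higher within the list. The camera adjusted p was 1.03e-07, and with an estimated correlation the adjusted p was 0.135. Y-linked transcripts, which depend on the sex of the embryos, did not pass over all genes but lay higher in the conditional knockouts. Their log2 fold changes were 0.61 (Ddx3y and Kdm5d), 0.62 (Uty) and 0.90 (Eif2s3y). Eif2s3y stood at 17.7, 20.01 and 40.96 FPKM in controls and at 34.1, 52.8 and 55.6 FPKM in conditional knockouts (limma adjusted p = 0.729). Missing the threshold does not show that the sexes were balanced.

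Genes of endothelial sprouting and coronary vessels went in both directions. Of 17 members, Esm1 rose, Gja4 fell and 15 did not pass over all genes. Adjusted over the list alone, 3 were higher, Esm1 together with the potassium channel subunit gene Kcne3 (2.09 ± 0.596 against 4.84 ± 0.848 FPKM in conditional knockouts) and the growth factor gene Pdgfb (1.28 ± 0.129 against 2.98 ± 0.653 FPKM), both markers of tip cells, and 1 was lower. The median was 0.08, and camera called the list higher (adjusted p = 0.00361). With an estimated correlation the camera adjusted p was 0.341, and it was 0.498 at a minimum mean of 5 FPKM and 0.0964 within replicates 2 and 3. The minimum of 5 FPKM leaves out Esm1, Kcne3 and Pdgfb, and other members on both sides of 0. Edn1, the endothelin 1 gene, had a log2 fold change of 0.75 ± 0.15 (SE, adjusted p = 0.233).

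In the angiopoietin and Tie group of 8 members, Tek fell and 7 did not pass, and adjusted over the list alone Tie1 was lower as well. Tie1, the receptor partner of Tie2, was at 24.7 ± 1.81 and 14.4 ± 0.898 FPKM (log2 fold change -0.74 ± 0.10, adjusted p = 0.0572 over all genes). Tie1 passed at a minimum of 5 FPKM (adjusted p = 0.0334), with quantile normalization (0.0478) and with the batch term (0.045), but in none of its 16 other alternatives, with an adjusted p of 0.0848 to 0.337 without any 1 library and of 0.662 with the Y-linked covariate. The ligand genes did not pass: Angpt1 stood at 27.0 ± 2.30 and 27.8 ± 2.79 FPKM, and Angpt2 at 0.833 ± 0.226 and 1.57 ± 0.334 FPKM (adjusted p = 0.718). The list median was -0.05 and camera placed it lower (adjusted p = 0.0423), but the list holds Tek, which was removed by design, and without Tek the call ended (adjusted p = 0.532). With an estimated correlation the adjusted p was 0.334, with the block 0.138, and 0.0621, 0.114, 0.136 and 0.0873 without control replicates 1 and 3 and conditional knockout replicates 1 and 2.

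No gene of the trabecular and neuregulin list passed over all genes among its 14 members, and camera did not call the list (median -0.08, adjusted p = 0.131), while fry called it in either direction (adjusted p = 0.0118). Nppa, the atrial natriuretic peptide gene that marks trabeculae, was at 739 ± 51.1 and 577 ± 65.97 FPKM (log2 fold change -0.36 ± 0.13, adjusted p = 0.736). Cited1, a transcriptional coregulator gene, was at 315 ± 37.1 and 204 ± 8.39 FPKM and was the member that passed when adjusted over the list alone. Bmp10, a trabecular growth factor gene, had a log2 fold change of 0.29 ± 0.22, Nrg1 one of -0.15 ± 0.19 and its receptor genes Erbb2 and Erbb4 -0.06 ± 0.11 and 0.17 ± 0.12 (SE). In the Notch pathway none of 17 genes passed (median -0.05, camera adjusted p = 0.714). Adjusted over the list alone, Dll1 and Notch1 were lower, with log2 fold changes of -0.83 ± 0.19 and -0.51 ± 0.13, while Hey2 stood at 38.4 ± 2.10 and 41.0 ± 4.61 FPKM.

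Of the 6 genes of the ventricular list, Irx5 fell and 5 did not pass, among them Irx4 at -0.30 ± 0.14 (median -0.25, camera adjusted p = 0.0122, and 0.453 with an estimated correlation). The RNA came from whole hearts, so the cells in which Irx5 fell are not known. Irx5 lay lowest at -0.97 and the other 5 between -0.34 and 0.09, and the list was not tested without Irx5. None of 21 sarcomere genes passed, 18 lay below 0, and camera placed the list lower (median -0.18, adjusted p = 0.00361, and adjusted p = 0.652 with an estimated correlation). Both calls were lost without either of 2 libraries. Without conditional knockout replicate 1 the adjusted p was 0.962 for the sarcomere and 0.205 for the ventricular list, and without control replicate 3 it was 0.0518 and 0.0533. Myl2, the ventricular myosin light chain gene, stood at 4047 FPKM in conditional knockout replicate 1 and between 5679 and 6777 FPKM in the other libraries. Within replicates 2 and 3 the adjusted p values were 0.283 and 0.0964. None of the 8 compact myocardium genes (median 0.02, adjusted p = 0.744), 7 atrial genes (0.01, adjusted p = 0.838) and 16 calcium handling genes (0.05, adjusted p = 0.677) passed. Their most abundant members Tbx20, Myl7 and Atp2a2 had log2 fold changes of 0.05 ± 0.11, 0.01 ± 0.19 and 0.07 ± 0.11 (SE). In the atrial list the mean, at -0.02, and the test lay on the other side of 0 from the median.

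Oxidative phosphorylation had no gene past the threshold among 18, with 17 below 0 (median -0.11, camera adjusted p = 0.011, and 0.552 with an estimated correlation). Cox8b, a subunit gene of cytochrome c oxidase, had the most negative value at -0.50 ± 0.11 (SE), and Atp5b, the most abundant, stood at -0.05 ± 0.17. The call ended without control replicate 1 (adjusted p = 0.237), without conditional knockout replicate 1 (0.208) and within replicates 2 and 3 (0.855), where the median was 0.02. Hypoxia and glycolysis had 14 of 21 members above 0 and none past the threshold (median 0.08, camera adjusted p = 0.0402, and 0.334 with an estimated correlation). Vegfa, at 0.65 ± 0.43 (SE), stood at 18.8 FPKM in control replicate 1 and at 54.1 and 65.5 FPKM in the other controls, and without control replicate 1 its value was 0.11. Aldoa, the most abundant, was at -0.16 ± 0.16 (SE). With the block the adjusted p of the list was 0.0501 and with no filter 0.0509. Without control replicates 2 and 3 it was 0.183 and 0.104, and without conditional knockout replicates 1 and 2 it was 0.15 and 0.0735.

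Among 25 genes of the cardiac jelly and extracellular matrix none passed and 18 lay below 0 (median -0.11, camera adjusted p = 0.0423, and 0.657 with an estimated correlation). The fibronectin gene Fn1 stood at 230 ± 36.6 and 159.98 ± 16.2 FPKM, the basement membrane collagen gene Col4a1 at 85.8 ± 10.8 and 64.3 ± 6.82 FPKM, and Sparc, the most abundant, at 473 ± 37.0 and 444 ± 32.5 FPKM (SD, n = 3 each). With the block its adjusted p was 0.0672, and it lay between 0.064 and 0.46 without each library other than control replicate 1. None of the 12 FoxO target genes passed and 11 lay below 0 (median -0.11, camera adjusted p = 0.0402, and 0.334 with an estimated correlation), with Foxo1 at -0.35 ± 0.10 and Txnip at -0.37 ± 0.22 (SE). The adjusted p was 0.0501 with the block, and without each library other than conditional knockout replicate 3 it lay between 0.0557 and 0.243. In the retinoic acid list none of 14 genes passed (median 0.13, camera adjusted p = 0.0304, and 0.552 with an estimated correlation). The binding protein gene Crabp2 stood at 4.01, 4.33 and 4.33 FPKM in controls and 21.6, 5.50 and 6.89 FPKM in conditional knockouts, and Aldh1a2, the synthesis enzyme gene, at 26.0 ± 1.48 and 29.7 ± 4.42 FPKM. The adjusted p was 0.434 without conditional knockout replicate 1, 0.133 and 0.0812 without control replicates 1 and 3, 0.0582 with the block and 0.96 within replicates 2 and 3.

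The lists for epicardium (13 genes, median -0.04, camera adjusted p = 0.838), cushion mesenchyme and EMT (19 genes, 0.07, 0.785), outflow tract and smooth muscle (9 genes, -0.23, 0.306), DNA replication (16 genes, -0.03, 0.744), mitosis (18 genes, 0.05, 0.642) and p53 targets and CDK inhibitors (14 genes, -0.12, 0.104) held no gene past the threshold and were not called by camera, while fry called the outflow tract list in either direction (adjusted p = 0.0217). For the epicardium the test pointed up while the median lay below 0. Their most abundant members were Upk3b (-0.19 ± 0.12), Postn (0.07 ± 0.43), Acta2 (-0.32 ± 0.21), Pcna (0.08 ± 0.17), Cdk1 (-0.01 ± 0.12) and the growth inhibitor gene Cdkn1c (-0.60 ± 0.16), each a log2 fold change with its SE.

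**Figure D2:**
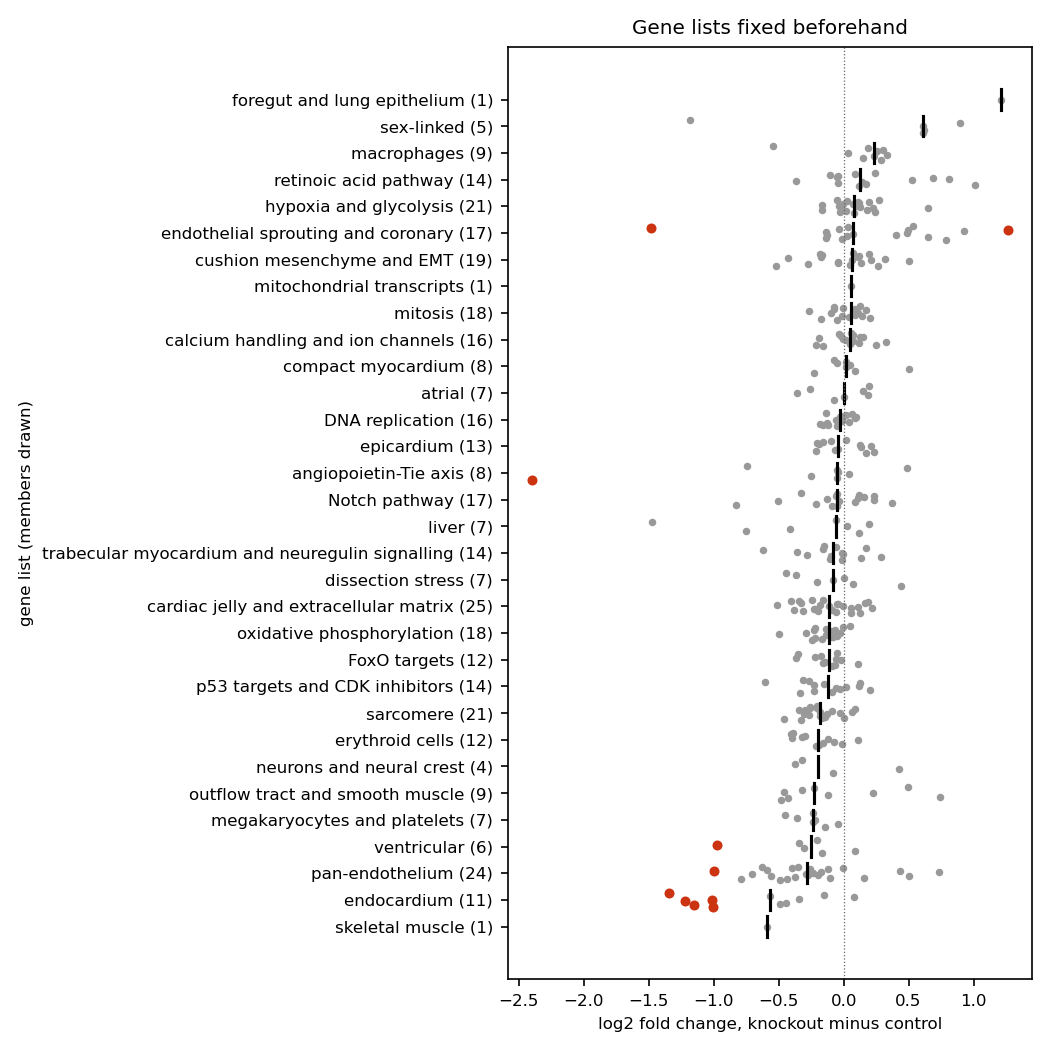
Log2 fold changes on the log2(FPKM + 1) scale of the members of 32 gene lists, without the genes listed at 0 in every control; grey points did not pass, red points passed an adjusted p of 0.05, and black bars are medians. The endocardial list holds 5 red points and a median of -0.57, and the pan-endothelial list a median of -0.28.

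Markers of other cells in the samples were also compared. Of 9 macrophage genes none passed, 8 lay above 0 and Lyz2, at -0.54 ± 0.13, was the exception and was lower when adjusted over the list alone. The complement gene C1qa stood at 3.03 ± 0.552 and 4.05 ± 0.394 FPKM and Csf1r, the receptor gene for macrophage growth factor, at 2.61 ± 0.302 and 3.40 ± 0.258 FPKM. The list median was 0.23 (camera adjusted p = 0.0223, and 0.453 with an estimated correlation). The adjusted p was 0.105 without control replicate 1, 0.0692 and 0.117 without conditional knockout replicates 1 and 2, 0.798 at a minimum of 5 FPKM and 0.177 within replicates 2 and 3. All 7 megakaryocyte and platelet genes lay below 0 and none passed, with Pf4 at -0.23 ± 0.21 (median -0.23, camera adjusted p = 0.0287, and 0.334 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.225), without conditional knockout replicates 1 and 3 (0.0692 and 0.0951) and at a minimum of 5 FPKM (0.293). The dissection stress list held 7 genes (median -0.08, adjusted p = 0.605), with Jun at 0.00 ± 0.14, and the list of neurons and neural crest 4 (median -0.20, adjusted p = 0.642), with Hand1 at -0.37 ± 0.15. The skeletal muscle list had 1 measured gene, Acta1, with a log2 fold change of -0.59 ± 0.19 (unadjusted p = 0.0166, adjusted p = 0.661 over all genes). The list of foregut and lung epithelium also had 1, Cldn6, at 6.50 FPKM in conditional knockout replicate 1 and at most 0.56 FPKM elsewhere.

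Liver transcripts varied between libraries of the same group. Afp, the alpha-fetoprotein gene, stood at 51.5, 11.2 and 15.7 FPKM in controls and at 2.204, 123 and 0.249 FPKM in conditional knockouts, and the 7 liver genes had a median of -0.06 (camera adjusted p = 0.838). Xist, the transcript of the inactive X chromosome in females, stood at 8.997, 40.7 and 0.0171 FPKM in controls and at 32.9, 0.0295 and 0.0324 FPKM in conditional knockouts. Equal portions of 1 RNA pool would share such values, so the libraries of a genotype differed by more than such portions would. Of the 5 sex-linked genes none passed (median 0.61, camera adjusted p = 0.0082, 0.334 with an estimated correlation and 0.0515 without control replicate 1). With the Y-linked covariate, the 15 lower genes other than Tek had a median log2 fold change of -1.07 in place of -1.15, a median SE of 0.169 in place of 0.121 and adjusted p values of at least 0.0892.

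**Figure D3:**
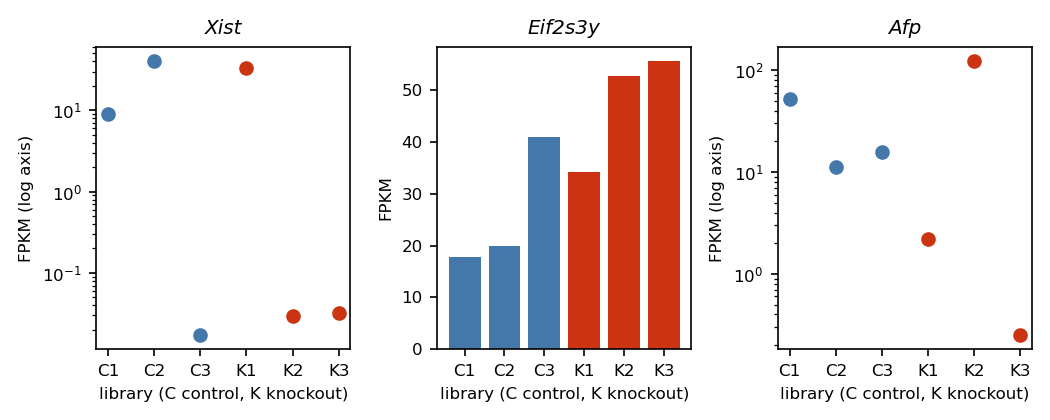
FPKM of Xist (log axis), the Y-linked Eif2s3y (bars from 0) and the liver gene Afp (log axis) in each library, with C for control and K for conditional knockout replicates. Xist was at 0.0171 FPKM in control replicate 3 and 40.7 FPKM in control replicate 2, and Afp ranged from 0.249 to 123 FPKM.

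The 6 genes listed at 0 in all 3 controls were the embryonic globin genes Hbb-y and Hba-x and the mitochondrial genes mt-Nd1, mt-Nd4, mt-Nd5 and mt-Nd6. In the conditional knockout libraries Hbb-y was listed at 17557, 23965 and 18968 FPKM, Hba-x at 11128, 18708 and 13568 FPKM, mt-Nd1 at 14287, 14518 and 15259 FPKM, mt-Nd4 at 9551, 8116 and 8963 FPKM, mt-Nd5 at 3278, 4137 and 5120 FPKM and mt-Nd6 at 11357, 5537 and 7344 FPKM. Mitochondrial genes are used by every cell, and 7 others were listed at 0 in all 6 libraries. Other genes of the same kinds had values in both groups: Hbb-bh1 stood at 5733 ± 1798 and 5271 ± 1631 FPKM, Hba-a1 at 4019 ± 1198 and 2986 ± 627 FPKM, and mt-Nd2 at 8012 ± 452 and 8357 ± 879 FPKM (SD, n = 3 each). Of 14 erythroid genes, 2 were among those listed at 0 and 12 did not pass, and the median of these 12 was -0.20. With all 14 the erythroid median was -0.17, while the mean was 1.83 and the test pointed up (camera adjusted p = 0.205). Of the 4 measured genes in the mitochondrial list, 3 were listed at 0 in controls. The camera call on that list (adjusted p = 4.79e-22, and 0.0524 with an estimated correlation) ended without the genes listed at 0 (adjusted p = 0.734).

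In all, camera with the preset correlation called 15 of the 32 lists, and none with an estimated correlation, where 3 had an unadjusted p under 0.05. Fry called 5 lists on balance 1 way, the angiopoietin and Tie, endocardial, pan-endothelial, erythroid and mitochondrial lists, and 10 lists in either direction, these 5 with the sprouting, trabecular, ventricular, outflow tract and macrophage lists. Its erythroid and mitochondrial calls ended without the genes listed at 0 in controls (adjusted p = 0.826 and 0.867 on balance, 0.689 each in either direction). Leaving out any 1 library kept the calls of the endocardial list (median between -0.73 and -0.48), the pan-endothelial list (between -0.34 and -0.28), the sprouting list (between 0.10 and 0.20) and the mitochondrial list. Of the 15 calls, 9, 12 and 7 held without control replicates 1, 2 and 3, and 5, 10 and 13 without conditional knockout replicates 1, 2 and 3. With the Y-linked covariate the camera calls of 5 lists ended, oxidative phosphorylation (adjusted p = 0.206), macrophages (0.403), hypoxia and glycolysis (0.0956), FoxO targets (0.144) and sex-linked genes (0.455). Further calls ended at a minimum of 5 FPKM (FoxO targets 0.0953, extracellular matrix 0.072), with a pseudocount of 0.1 (angiopoietin and Tie 0.0522, extracellular matrix 0.0567), with quantile normalization (FoxO targets 0.0518, extracellular matrix 0.117), with rescaling without blood and mitochondrial transcripts (FoxO targets 0.0557, retinoic acid 0.0673) and within replicates 2 and 3 (FoxO targets 0.0964, angiopoietin and Tie 0.186, sex-linked genes 0.112). The batch term for replicate 1 kept 13 of the 15 camera calls and ended those of angiopoietin and Tie (adjusted p = 0.138) and extracellular matrix (0.0587).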

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

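The alternatives added after the data were seen are leaving out the genes listed at 0 in 1 group, the Y-linked covariate, the batch term, leaving out Tek, fry without the genes listed at 0, and replicates 2 and 3 alone. No called gene changed direction under any alternative run and no called list did in camera, although the median of oxidative phosphorylation went from -0.11 to 0.02 within replicates 2 and 3. Under the scaling, pseudocount, trend and batch-term alternatives the counts stayed within 1.5 times of 16 lower and 7 higher genes, at any fold and at a minimum of 1.5-fold alike. Single calls still ended in limma: Bace2 (adjusted p = 0.0834), Tmem100 (0.0594) and Col13a1 (0.0564) with rescaling without blood and mitochondrial transcripts. Bace2 (0.056) and Lgals9 (0.0531) lost theirs without the intensity trend, and Bace2 (0.0526) with quantile normalization. With no filter on low values, where more genes are tested, 7 genes were lower at either minimum. Leaving out 1 library gave 4 to 9 lower and 6 to 11 higher genes at either minimum, and 7 to 14 lists that differed, with fewer samples in the fit. Of the 16 lower genes, 8, 2 and 6 remained lower without control replicates 1, 2 and 3, and 5, 5 and 3 without conditional knockout replicates 1, 2 and 3, with Tek and Npr3 past the threshold in each. With the replicate block, which uses up residual degrees of freedom, limma called 11 lower and 6 higher genes and camera called 10 lists. It ended no other call than those given in the report and added 1 lower gene, the microRNA gene mmu-mir-8112. Without the genes listed at 0, 1 gene was higher, as those genes were the others, and 15 were lower. With the Y-linked covariate 1 gene was lower. Without Tek 15 genes were lower and 14 lists differed. Within replicates 2 and 3, 8 genes were lower, 9 lists differed and Tek had a log2 fold change of -2.39 (adjusted p = 0.0546, with 0.000368 to 0.0546 over its 18 alternatives), with fewer samples. The estimated correlation left 0 lists, fry 5 and fry without the genes listed at 0 left 3, and the cause was not tested. Over its alternatives the change of Tek ranged from -2.69 to -2.07. Absolute depth is unknown, so no limit of detection can be given for genes listed at 0.

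Chance was tested with the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. For the lower genes 1 split, the real one, gave as many as 16, and the other splits gave at most 2 in their larger direction. For the higher genes 1 split reached 7, with at most 2 elsewhere, and both results were the same at a minimum of 1.5-fold. Of these 7 genes, 6 were listed at 0 in every control. Any other split mixes 0 with high values of these genes in 1 set, so only the real split could call them. Without them the real split had 1 higher gene, so the splits say nothing for the higher genes. For the lists 1 split reached 15, and the highest other gave 13. The 3 other splits that also part all 3 same-numbered pairs gave at most 2 genes in 1 direction and at most 13 lists.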

Other observations

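The tests of all endothelial cells, of the sex of the embryos, of the genes listed at 0 and of the Hox genes were chosen after the results were seen, and that of linked strain DNA before. Beyond the genes past the threshold, 35 lower and 4 higher genes had an unadjusted p under 0.001 without passing the adjustment in limma. Of these, Nos3, Vwf, Ecm1 and Sall1 are named here after their values were seen. Nos3, the endothelial nitric oxide synthase gene, stood at 11.3 ± 1.03 and 5.93 ± 0.617 FPKM (log2 fold change -0.83 ± 0.11, adjusted p = 0.0582, and 0.0508 to 0.776 over its alternatives). Vwf, which encodes von Willebrand factor, was at 10.8 ± 0.473 and 5.31 ± 1.28 FPKM (adjusted p = 0.135), and Ecm1, an extracellular matrix gene, at 46.4 ± 2.603 and 26.2 ± 3.87 FPKM (adjusted p = 0.104). The transcription factor gene Sall1 had a log2 fold change of -0.67 ± 0.10 (adjusted p = 0.0877). Irx3, the neighbour of Irx5 and Irx6 on chromosome 8 (91798525 to 91802067), had a value of -0.28 ± 0.12 (adjusted p = 0.748).

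The first pattern weighed is the fall of 15 genes other than Tek, whose mean lay -1.17 ± 0.044 below control on the log2 scale (SE). A difference in the sex of the embryos was tested with the Y-linked score as a covariate. The difference of the 15 genes was then -1.11 ± 0.0488 (SE). Their single calls ended as the SE grew, the score being correlated with the group at 0.71. The 15 genes were chosen for a group difference that is large against their spread within groups in these same libraries. This test therefore cannot decide whether the sex of the embryos plays a part. Strain DNA carried along with the altered alleles would place the genes near Tek or Nfatc1, yet 0 of the 15 lay within 20 Mb of either, the nearest on the chromosome of Tek being Gja4 at 32.6 Mb. The Cre allele was taken to lie at Nfatc1, which was not checked, so DNA linked to a Cre elsewhere stays open. A lower share of all endothelial cells was tested on the endocardial and pan-endothelial lists, which were fixed before the data were examined. The 11 endocardial genes had a mean difference of -0.695 ± 0.0459 and the 24 pan-endothelial genes one of -0.257 ± 0.0419, so that the endocardial genes lay -0.439 further down, with an SE of 0.00981 over libraries and 0.166 over genes. A lower share would lower both alike if endothelial cells alone expressed both lists. Genes of the pan-endothelial list that other cells also express would fall by less, which was not tested. The limit of 2 SE was set after these values were seen, as were 2 earlier ones, 0.5, which was not reached, and 0.2, which was reached and withdrawn. The result depends on that choice, so the test cannot decide whether a lower share is the whole cause of the lower endocardial list. A lower share also stays open for the lower genes outside both lists. A change of expression within the endocardium and a loss of endocardial cells alone also stay open and were not tested. An effect of the Cre allele itself was not tested either.

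The second pattern is the set of 6 genes listed at 0 in the controls alone. More blood cells in the conditional knockout hearts would raise the other erythroid genes, whose median log2 fold change was -0.199 with an SD of 0.165, and 11 of 12 lay below 0. Failed estimates of very abundant genes in the authors' processing are a candidate explanation, since 7 of the 13 mitochondrial protein genes were listed at 0 in all 6 libraries. What step failed in the control libraries was not tested.

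The third pattern concerns Hox genes, which pattern the body axis. All 10 measured genes of paralog groups 2 to 5 had a positive log2 fold change and none passed, with Hoxa5 at 1.81, 1.66 and 2.04 FPKM in controls and 4.17, 3.53 and 6.18 FPKM in conditional knockouts (adjusted p = 0.205) and Hoxa4 at 1.28, 1.22 and 1.56 against 6.43, 2.53 and 4.07 FPKM. Hoxa2, Hoxa3, Hoxb3, Hoxb4, Hoxc4 and Hoxc5 had control means under 1 FPKM and passed the filter on the mean only through the conditional knockouts. For these genes a higher conditional knockout mean follows from the filter. Tissue from outside the heart in conditional knockout replicate 1, where Isl1 and Stra6 were also highest at 10.5 and 4.49 FPKM, may explain part of the higher Hox values. Without that library the median of the 5 genes of groups 4 and 5 was 0.851, with all 5 above 0, and that of the 5 genes of groups 2 and 3 was 0.295, with 4 of 5 above 0. The genes and their grouping were chosen after their values were seen, so for both groups such tissue cannot be told apart from other causes. A difference in dissection between the groups and an effect of the genotype both stay open and were not tested.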
